A study of Mus musculus with 3 samples.

How the data were processed

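Oocytes of female ICR mice were profiled in 3 libraries of total RNA taken with Trizol and prepared for Illumina sequencing, per the labels' protocols. Groups followed the exposure label of each sample (none, low or high), with 1 library per group. HISAT2 and StringTie are named in the submitters' processing notes, with the mouse build mm10. Their versions, the annotation, the trimming, the strand setting and the read layout are not given in the sources used here.

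The authors deposited FPKM values, per the file headers, in 1 table per library with a gene identifier, a gene name and the value. Most identifiers were loci numbered by the assembler, and others were Ensembl identifiers. There were 41258 rows for the control library and 41310 for each exposed library, of which 39222 were in all 3. No shared row was at 0 in both control and low dose or in both exposed libraries. The 2088 rows that only the exposed tables listed were all at 0 in the low dose library. Rows absent from a table were therefore taken as 0 in it. Tables were joined by identifier. A set of 61 identifiers carried different names in the control and exposed tables and was left out; these held 0.10, 0.13 and 0.12% of the FPKM of the control, low dose and high dose libraries. Rows without a gene name, 12431 in all, held 15.4, 21.9 and 19.3% of the FPKM and were left out of the main counts. An exact 0 in such a table can be a failed estimate, so a gene at 0 is given as listed at 0, or as taken as 0, with each library's value and no fold.

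From the deposited FPKM, values were summed per gene symbol, which gave 23376 symbols. Genes with a mean of at least 1 FPKM over the 3 libraries (12151, of which 4226 had several rows) were called expressed. The log2 ratio of 2 libraries was taken after adding 1 FPKM, values as deposited, and a gene was called higher or lower at a log2 ratio of at least 1 in size. Summed FPKM differed between libraries (377415, 424756 and 393864). FPKM is not a count, so no count test was run. Depth was estimated from genes with 1 transcript in the reference, whose FPKM times length was assumed to be a whole multiple of the worth of 1 read. The most crowded narrow window of these products was taken as 1 read. It held 147 of 1399, 96 of 1022 and 110 of 1223 rows in the control, low dose and high dose libraries. The depths so obtained were 34700000, 27900000 and 31500000, and whether the units are reads or fragments is open. The assumption of whole multiples was not tested. The worth of 1 read bounds counting error only, and molecules were not told apart from copies.

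Each gene list was fixed before the data were examined. The 30 lists covered oocyte-specific factors, maternal-effect genes, meiotic maturation, the spindle, maternal mRNA storage and decay, DNA methylation enzymes, histone-modifying enzymes, imprinted genes, mitochondrially encoded mRNAs, oxidative phosphorylation, mitochondrial dynamics, glycolysis and the tricarboxylic acid cycle, antioxidant defence, the xenobiotic response, hormone receptors, apoptosis, DNA repair, the unfolded protein response, autophagy, ribosomal proteins, the proteasome, cholesterol synthesis, housekeeping genes, 2-cell genes and markers of 6 other kinds of cell. For the 24 lists with at least 5 expressed members, the median log2 ratio was placed as a percentile among 10000 random lists of equal size matched on mean expression in 10 bins. A list stood apart below percentile 2.5 or above 97.5. With independent genes 5% of lists would do so by chance, and members that vary together raise that share.

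Named genes followed a rule fixed before the data were examined. For each pair of libraries the 10 largest positive and the 10 largest negative log2 ratios were named among genes with a mean of at least 5 FPKM and a curated symbol. From each list up to 4 members with the largest ratios against control were added, together with 20 fixed genes and the 10 genes that moved most in each direction at both doses. Some of the genes this rule names are not reported here. Positions, transcript lengths (the longest transcript) and exon numbers came from GENCODE release M21 on GRCm38, the assembly also called mm10, and 96.4% of expressed symbols had a length.

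Overlap of the comparisons with control was set beside 100 simulations of exchangeable libraries that share a control, on values as deposited and, chosen after seeing the data, after each scaling. Alternatives were other pseudocounts, filters, thresholds, scalings, bins and ways to join rows. The largest row per gene, rows in all 3 tables only, unnamed rows added, ratios adjusted for transcript length and lists matched on length were chosen after seeing the data.

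The rule and the list percentile were tested on simulated data over 12151 genes, with 200 genes changed. For the low dose comparison 34.0, 90.0 and 100% of genes changed 2-, 4- and 8-fold passed the 2-fold rule, and for the high dose comparison 42.0, 96.0 and 100%. For high against low dose the shares were 26.0, 96.0 and 100%. Unchanged genes passed it in 6.9, 2.9 and 1.3% of cases in these comparisons. The simulated noise was normal, independent between genes and set from the spread of the observed log2 ratios themselves. These shares are thus not error rates of the observed counts, for which replicates would be needed. Lists of 30 genes without a shift stood apart in 6.0, 4.5 and 4.0% of cases, and lists shifted by 0.5 in 99.5, 100 and 100%. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.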

Results

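RNA sequencing was carried out on oocytes of female ICR mice, an outbred strain, at 8 weeks of age. The 3 libraries formed 3 groups with 1 library each, namely a control without exposure, a low dose of PCB118 and a high dose of PCB118. PCB118 is a chlorinated biphenyl of the dioxin-like class. The labels call the doses low and high without amounts, and the series title places the exposure in pregnancy and asks how oocytes of the offspring mature. With 1 library per group, no difference had a replicate check and no p-value is given, so every statement describes these libraries and not the conditions. Expression was given as FPKM (fragments per kilobase of transcript, scaled to the size of the library), and log2 ratios were taken on the log2(FPKM + 1) scale, which understates the change of low genes. A gene was counted as higher or lower when its log2 ratio was at least 1 in either direction, a rule of size and not a test.

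The most common low value, taken as the worth of 1 read, placed the depth of the control, low dose and high dose libraries at about 34700000, 27900000 and 31500000 reads. At these depths 1 read over a transcript of 1 kb was worth 0.0288, 0.0359 and 0.0318 FPKM. Gene symbols at 1 FPKM or more numbered 11272 in the control library, 12335 in the low dose library and 11786 in the high dose library. Across the 3 libraries 12151 symbols had a mean of at least 1 FPKM, and these are the expressed genes of all counts. The 20 most abundant symbols held 15.1% of the named FPKM in control, 11.7% at the low dose and 12.9% at the high dose.

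Several transcripts that mark oocytes were abundant in all 3 libraries, and others were not. Dppa3, a maternal factor that protects DNA methylation in the zygote, was at 4707, 4174 and 5342 FPKM in the control, low dose and high dose libraries, the order kept for all values that follow. Genes of the zona pellucida, the glycoprotein coat of the egg, lay close together, with Zp1 at 100.4, 119 and 105 FPKM, Zp2 at 320.3, 379.6 and 353 FPKM and Zp3 at 712, 699.9 and 571 FPKM. Nlrp5, a subunit of the subcortical maternal complex, was at 62.9, 79.2 and 76.4 FPKM, and Kit, the receptor of Kit ligand, at 4.07, 5.41 and 3.26 FPKM. Gdf9 (row MSTRG.6985; reference gene at chromosome 11, 53431023 to 53437904, plus strand, GRCm38) was at 661, 38.5 and 193 FPKM, with log2 ratios to control of -4.06 and -1.77, whereas Bmp15 was at 4.27, 18.7 and 15.8 FPKM, with log2 ratios of 1.90 and 1.67. Bmp15 was listed in 2 rows, of which 1 held 4.14, 18.7 and 7.44 FPKM and the other 0.13, 0 and 8.34 FPKM. The larger row alone gave a log2 ratio of 0.71 at the high dose, below the rule.

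Among the DNA methyltransferases, Dnmt1, which maintains methylation at replication, was at 62.9, 63.1 and 56.5 FPKM, and Dnmt3l, the cofactor of de novo methylation in oocytes, at 14.9, 14.3 and 13.6 FPKM. Dnmt3a, the de novo enzyme of oocytes, was at 4.67, 9.40 and 7.41 FPKM (log2 ratios 0.87 and 0.57), and Dnmt3b at 1.23, 1.60 and 1.02 FPKM. None of these 4 genes passed the 2-fold rule against control. The TET enzymes, which oxidise methylated cytosine, gave 10.1, 15.5 and 19.2 FPKM for Tet3, 4.61, 2.07 and 5.16 FPKM for Tet1 and 1.47, 4.83 and 1.08 FPKM for Tet2. Tet2 was higher than control at the low dose (log2 ratio 1.24), but its largest row alone, of 4, did not pass the rule (0.52). Tet1, spread over 4 rows, changed direction at the high dose when its largest row alone was used (log2 ratio -1.28 in place of 0.14).

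Ligand-activated receptors were expressed at modest levels. Ahr, the aryl hydrocarbon receptor, was at 2.21, 3.86 and 5.85 FPKM, with log2 ratios to control of 0.60 and 1.09. The larger of its 2 rows alone gave 0.83 at the high dose, below the rule. Cyp1a1, a classical target of this receptor, was among the fixed genes but had no row under that name among the rows used here. Cyp1b1 was at 0.083, 0.11 and 0.38 FPKM. Esr2, oestrogen receptor beta, was at 9.76, 7.09 and 29.3 FPKM, higher at the high dose (log2 ratio 1.49), and Esr1, oestrogen receptor alpha, was at 2.16, 1.82 and 1.64 FPKM. The 2 rows of Esr1 moved in opposite directions, 1 at 1.43, 0.56 and 0.30 FPKM and the other at 0.73, 1.26 and 1.34 FPKM.

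**Figure D1:**
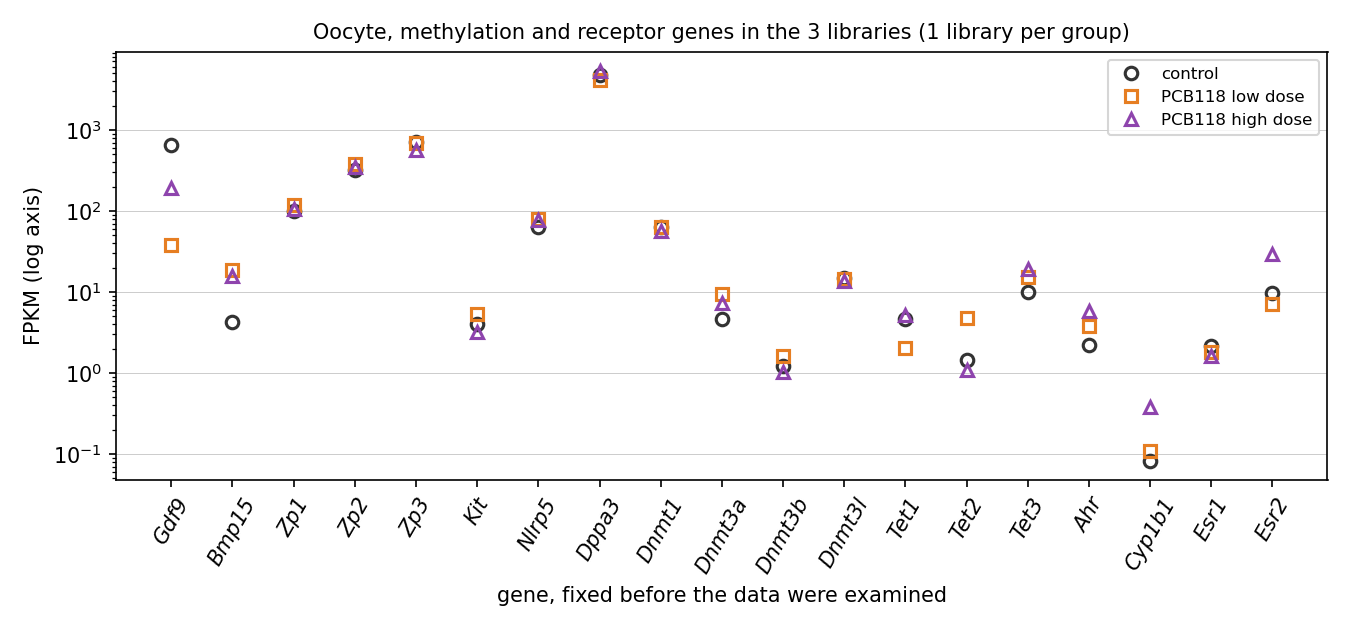
FPKM of 19 genes fixed before the data were examined (horizontal axis) in the control, low dose and high dose libraries, on a log axis; each symbol is 1 library, with no error bar because each group had 1 library. Gdf9 spans 661 to 38.5 FPKM, while Zp3 lies between 571 and 712 FPKM.

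The low dose library was compared with control to describe the transcripts that differed at the smaller exposure. Ubiquitin-proteasome genes, oocyte-specific factors and antioxidant enzymes were lower as groups than in control, and histone-modifying enzymes were higher as a group. Of these calls that of histone-modifying enzymes ended under both corrections for transcript length given below, and those of oocyte-specific factors and antioxidant enzymes under 1 of them. Among single genes, Tead1, the DNA-binding partner of YAP in the Hippo pathway, was at 0.39 FPKM against 42.0 FPKM in control (log2 ratio -4.95), and Cdc5l, a core splicing factor, at 3.51 against 97.9 FPKM (log2 ratio -4.46). Mos, the kinase that holds eggs at metaphase II, was at 178 against 9.36 FPKM (log2 ratio 4.11). Of 12151 expressed genes, 1766 were at least 2-fold higher and 710 at least 2-fold lower, so 71.3% of the genes past the rule were higher.

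That split moved with scaling. The median log2 ratio of all expressed genes was 0.17, and a trimmed mean scaling brought it to 0.02, with 1401 genes higher and 898 lower (60.9% higher). For a list whose median against control changed sign under trimmed mean scaling, the scaled median is given too.

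The largest positive log2 ratios in the low dose library belonged to Dytn (73.4 against 0.27 FPKM, log2 ratio 5.87), Igf2bp1, an mRNA-binding protein (65.9 against 0.44, 5.54), Evx1os, an antisense transcript of Evx1 (78.9 against 0.71, 5.54), and Ccdc6 (66.9 against 0.57, 5.44). Fam76a (36.3 against 0.054, 5.14), the corepressor Rere (126 against 3.18, 4.93) and Rc3h1, the RNA-decay factor roquin (67.9 against 1.42, 4.83), followed. Pcbp1 was listed at 0, 97.1 and 0 FPKM, the mitochondrial tRNA mt-Tf at 0, 69.4 and 0 FPKM and Them7 at 0, 35.4 and 0.60 FPKM, so no ratio to control is given for these 3. The largest negative log2 ratios belonged to Tmem261 (0.35 against 105 FPKM, -6.30), Usp50 (0.16 against 77.6, -6.08), the transcription factor Atf7 (4.13 against 173, -5.08), Uevld (1.24 against 54.4, -4.63) and Prcc (0.21 against 22.7, -4.29). Rn7s2, a copy of the signal recognition particle RNA, had 16.9 FPKM in control and a value near 0 at the low dose. Muc13 was listed at 235, 0 and 265 FPKM, and mt-Tt, a mitochondrial tRNA, was at 28.9 FPKM in control and taken as 0 in both exposed libraries. The largest row was at 0 in control for Evx1os and Fam76a and at the low dose for Uevld, and was taken as 0 there for Prcc, so their ratios rest there on smaller rows. Of the 10 genes with the largest positive and the 10 with the largest negative ratios, 9 and 7 had several rows or a single exon.

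Of 32 expressed members of the ubiquitin-proteasome list, 28 lay below the median of all genes in the low dose library, a count not corrected for transcript length. The median of all genes was 0.17, against -0.03 in the fifth of genes nearest this list in length (median 1811 bases). The list had a median log2 ratio of -0.39, at percentile 0.01 of 10000 random lists matched on expression. Only 1 member, Ubb, a polyubiquitin gene, passed the 2-fold rule (727 against 1708 FPKM). Psmb1, a subunit of the catalytic core, was at 451 against 787 FPKM, and Psmc4, an ATPase of the regulatory particle, at 29.9 against 57.0 FPKM. Oocyte-specific factors (29 expressed, 2 higher and 3 lower) had a median of -0.35 at percentile 0.24. Astl, the protease ovastacin that cleaves the zona pellucida, was at 2.75 against 17.3 FPKM (log2 ratio -2.29), and Figla, a transcription factor of zona genes, at 73.4 against 95.8 FPKM. Antioxidant genes (28 expressed, 1 higher and 2 lower) had a median of -0.22 at percentile 1.01. The call ended with the largest row per gene (percentile 3.92) and with a mean of at least 5 FPKM (8.04). Within this list Nqo1, a quinone reductase, was at 0.82 against 4.88 FPKM (log2 ratio -1.69). Histone-modifying enzymes (39 expressed, 3 higher and 1 lower) had a median of 0.47 at percentile 98.8, with Setd1b at 3.40 against 0.28 FPKM and Setd2, the H3K36 methyltransferase, at 12.3 against 6.50 FPKM. Of the Setd1b value 2.28 FPKM came from a row listed at 0 in control, and its other row was at 1.12 against 0.28 FPKM. Once random lists were also matched on transcript length, the percentiles were 0.22 for the proteasome, 1.74 for oocyte-specific factors, 2.22 for antioxidant genes and 94.7 for histone-modifying enzymes. With ratios adjusted for length they were 1.36, 7.07, 6.69 and 94.2, so of these 4 the proteasome list alone stood apart under both.

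Meiotic and mRNA-control lists did not stand apart at the low dose without a correction for length but held single genes past the rule. Meiotic maturation genes (33 expressed, 4 higher and 3 lower) had a median of 0.16 at percentile 66. Cks1b, a subunit that binds cyclin-dependent kinases, was at 96.5 against 425 FPKM (log2 ratio -2.13), the phosphatase Cdc14b at 161 against 68.6 FPKM (1.22) and the kinase Wee1 at 5.32 against 1.55 FPKM (1.31). Spindle genes (34 expressed, 0 higher and 2 lower) had a median of -0.10 at percentile 8.09, or 1.32 when length was matched too and 0.24 with ratios adjusted for length, so it stood apart under both corrections and not without them. Spire1, an actin nucleator of the spindle migration, was at 4.69 against 15.6 FPKM (-1.54), and Aurkc, the meiotic Aurora kinase, at 16.5 against 33.4 FPKM. Kif4, a chromokinesin, was at 21.6 against 49.6 FPKM, but of its 2 rows 1 gave 17.6 against 13.5 FPKM and the other 4.00 against 36.1 FPKM. Genes of maternal mRNA storage and decay (25 expressed, 3 higher and 1 lower) had a median of -0.11 at percentile 7.07. Cnot6l, a deadenylase of the egg, was at 42.3 against 9.48 FPKM (2.05), the uridylyl transferase Zcchc11 at 43.3 against 5.66 FPKM (2.73), the m6A reader Ythdf2 at 106 against 38.3 FPKM (1.44) and Eif4enif1 at 3.96 against 17.0 FPKM (-1.86).

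**Figure D2:**
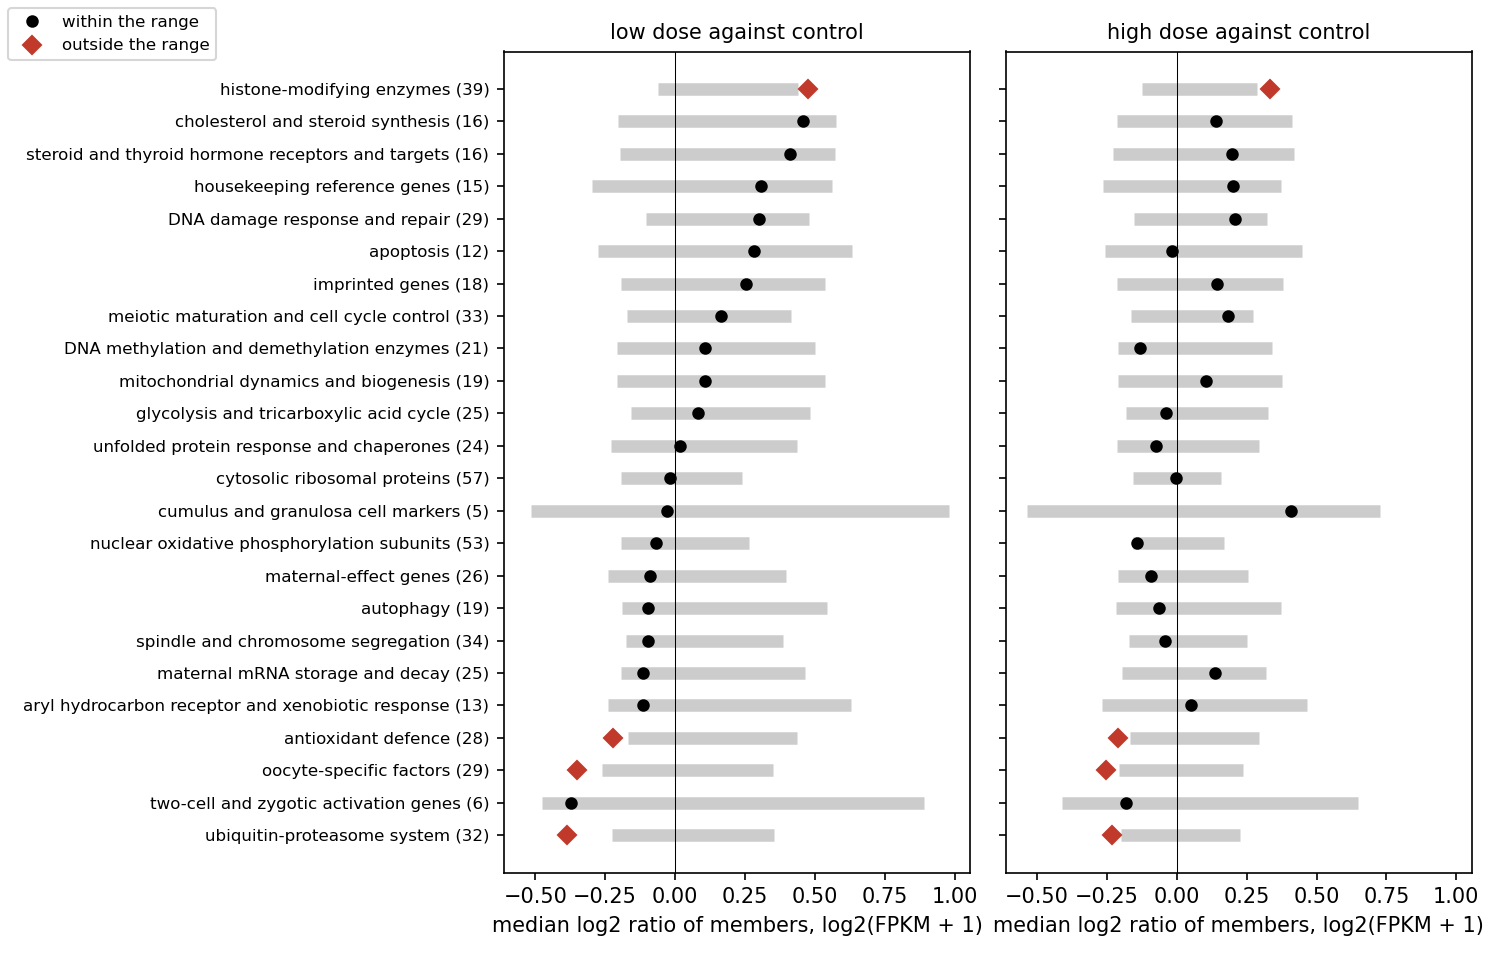
Median log2 ratio, on the log2(FPKM + 1) scale, of the expressed members of each of 24 gene lists (number of members in brackets) in the low dose and high dose libraries against control; points are the medians and grey bars the central 95% of 10000 random lists matched on expression. In both panels, which share the single control library, the proteasome, oocyte-specific and antioxidant lists lie below their bars and the histone-modifying list above.

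The high dose library was compared with control in the same way. Oocyte-specific factors, ubiquitin-proteasome genes and antioxidant enzymes were lower as groups here too and histone-modifying enzymes higher. None of these 4 lists stood apart under both corrections for transcript length. Both comparisons used the single control library, so the recurrence of these lists is not an independent repetition. Sall4, a zinc finger factor of germ cells and early embryos, was at 0.43 FPKM against 42.0 FPKM in control (log2 ratio -4.91). Uhrf1, which brings Dnmt1 to replicated DNA, was at 5.72 against 54.6 FPKM (-3.05), and Ccnk, cyclin K, at 2.31 against 75.6 FPKM (-4.53). Of 12151 expressed genes, 1155 were at least 2-fold higher and 629 at least 2-fold lower, and the median of all genes was 0.08. Trimmed mean scaling gave 1022 higher and 698 lower, with a median of 0.01.

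Hist1h2bc, a histone H2B gene, had the largest positive log2 ratio at the high dose (62.2 against 0.54 FPKM, 5.36). Triap1, an inhibitor of apoptosis (57.9 against 0.60, 5.20), the heparan sulfatase Sulf2 (69.1 against 1.12, 5.04), Evx1os (54.9 against 0.71, 5.03), the RNase P subunit Rpp38 (108 against 2.33, 5.03) and Heatr5a (43.8 against 0.49, 4.91) came next. Rc3h1 (4.84), the lysosomal enzymes Gla (29.6 against 0.12, 4.77) and Hgsnat (40.5 against 0.62, 4.68), and Rraga, listed at 0, 0.66 and 25.4 FPKM, completed the 10. On the lower side stood Tuba1c, an alpha tubulin (1.00 against 48.8, -4.64), Tmem131 (2.46 against 81.1, -4.57), Bola1 (1.84 against 63.6, -4.51) and Pappa2 (0.61 against 35.0, -4.48). Prcc (-4.34) and Mrpl36, a protein of the mitochondrial ribosome (0.34 against 23.8, -4.21), were also among them. Rn7s1 was listed at 17.2, 2.80 and 0 FPKM, and mt-Tt was taken as 0. The largest row was listed at 0 in control for Evx1os, Gla and Hgsnat and at the high dose for Ccnk, Tmem131 and Pappa2, and was taken as 0 at the high dose for Prcc. Several rows or a single exon were found for 7 of the 10 on the higher side and 6 of the 10 on the lower side.

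Oocyte-specific factors (1 higher and 3 lower of 29) had a median of -0.25 at percentile 0.79 in the high dose library, with Figla at 41.8 against 95.8 FPKM (-1.18) and Astl at 4.29 FPKM (-1.79). Proteasome genes, with 0 of 32 past the rule and 29 below the median of all genes (not corrected for length), had a median of -0.23 at percentile 1.14. Antioxidant genes (0 higher and 3 lower of 28) had a median of -0.21 at percentile 1.02, a call that ended with a mean of at least 5 FPKM (5.10) and with genes held by 1 list only (4.15). Glrx, glutaredoxin, was at 51.5 against 521 FPKM (-3.31), the extracellular peroxidase Gpx3 at 0.22 against 3.80 FPKM (-1.97) and metallothionein Mt2 at 1.73 against 5.47 FPKM (-1.25). Histone-modifying enzymes (4 higher and 3 lower of 39) had a median of 0.33 at percentile 99.1, with Setd2 at 34.2 against 6.50 FPKM (2.23), and the H3K9 demethylases Kdm3a at 6.77 against 0.71 FPKM (2.18) and Kdm4c at 9.83 against 1.18 FPKM (2.31). Within Setd2 the difference lay mainly in 1 row, at 27.6 against 2.55 FPKM, while another was at 4.98 against 3.59 FPKM. It lay in 1 row also for Kdm3a (6.59 against 0.46 FPKM) and Kdm4c (9.68 against 1.16 FPKM). With the largest row per gene the percentile of the histone-modifying list was 97.4 and the call ended. Matched on length as well, the 4 percentiles in this order were 4.87, 4.79, 2.21 and 97.7. With ratios adjusted for length they were 2.98, 2.27, 6.0 and 94.1, so no list stood apart under both.

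Maternal-effect genes (26 expressed, 1 higher and 3 lower at either dose) had medians of -0.09 and -0.09 at percentiles 19.8 and 18.1. Sebox, an oocyte homeobox gene, was at 17.4, 2.42 and 0.59 FPKM, with log2 ratios of -2.43 and -3.53, and Tcl1, a coactivator of AKT, at 202, 95.3 and 609 FPKM, with log2 ratios of -1.08 and 1.59. DNA methylation enzymes (21 expressed) had a median of 0.11 at the low dose, which became -0.10 under trimmed mean scaling, and of -0.13 at the high dose, at percentiles 45.3 and 8.39. In this list 4 genes were higher and 1 lower at the low dose, against 0 and 1 at the high dose. Uhrf1 was at 54.6, 126 and 5.72 FPKM, Uhrf2 at 0.65, 3.14 and 0.76 FPKM and Trim28, the corepressor of imprinted loci, at 55.5, 18.4 and 75.7 FPKM, where 1 row held 17.0, 18.4 and 16.3 FPKM and another 38.5, 0 and 58.1 FPKM.

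Subunits of oxidative phosphorylation encoded in the nucleus (53 expressed) had medians of -0.07 and -0.14 at percentiles 21.2 and 3.98. At the high dose this list stood apart with rows kept separate (percentile 1.21) and with the largest row per gene (2.40). Cox8a was at 186, 44.5 and 18.8 FPKM, with log2 ratios to control of -2.04 and -3.24, but 1 of its 2 rows gave 21.1, 43.9 and 18.3 FPKM and the other 164.4, 0.60 and 0.54 FPKM. Ndufa1 (159, 516 and 439.8 FPKM) and Ndufa2 (468, 1243 and 1118 FPKM) were higher than control at both doses, and Uqcrfs1 was at 0.15, 27.6 and 0.60 FPKM. Of the 13 mRNAs encoded by mitochondrial DNA, 5 were analysed here and 2 had a mean of at least 1 FPKM, namely mt-Co1 at 19.1, 7.99 and 7.61 FPKM and mt-Cytb at 1.87 and 3.57 FPKM in control and low dose and near 0 at the high dose. Whether reads from mitochondrial DNA were filtered is not given in the sources used here, which limits what these values mean. Cytosolic ribosomal proteins (57 expressed) had medians of -0.02 and 0.00, with Rpl26 at 38.0, 40.4 and 126 FPKM, Rpl30 at 42.3, 26.3 and 18.2 FPKM, Rpl9 at 3.10, 7.45 and 5.80 FPKM and Rps9 at 108, 58.1 and 58.9 FPKM.

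The xenobiotic list (13 expressed) had medians of -0.12 at the low dose and 0.05 at the high dose, the latter turning to -0.01 under trimmed mean scaling, at percentiles 7.4 and 40.6. Higher than control were 2 members at the low dose and 3 at the high dose, while 2 and 1 were lower. Abcc2, an efflux transporter, was at 0.98, 4.37 and 4.68 FPKM, and Arnt, the dimer partner of the aryl hydrocarbon receptor, at 0.75, 0.48 and 3.02 FPKM. Hormone receptors and their targets (16 expressed) had medians of 0.41 and 0.20 at percentiles 87.9 and 76.6, with 3 and 2 members higher and 0 lower. Without a filter on low values this list stood apart at the low dose (percentile 98.8). The coactivator Ncoa1 was at 7.19, 16.03 and 27.9 FPKM, the corepressor Ncor1 at 3.16, 10.5 and 3.47 FPKM and Klf9, a target of thyroid hormone, at 0.22, 4.87 and 0.12 FPKM.

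**Figure D3:**
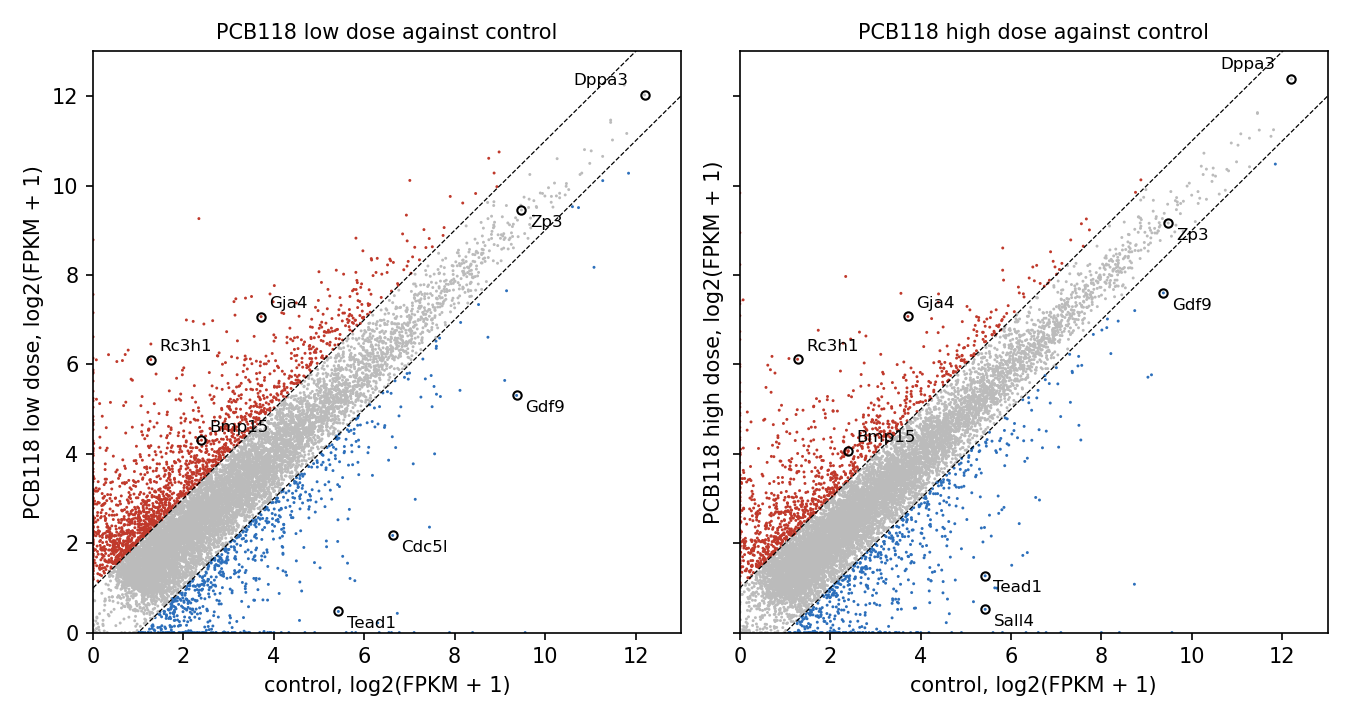
Expression of 12151 genes in the low dose (left) and high dose (right) libraries on the vertical axis against control on the horizontal axis, each as log2(FPKM + 1); each point is 1 gene, red at least 2-fold higher, blue at least 2-fold lower, with dashed lines at the 2-fold rule. Gdf9 and Tead1 lie below the lower line and Gja4, Rc3h1 and Bmp15 above the upper line in both panels.

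Genes that differed from control in both exposed libraries were then counted. Rc3h1, Evx1os and Triap1 were higher at both doses, and Tead1, Cdc5l and Prcc were lower at both doses. Gja4, connexin 37, which forms the gap junctions between the oocyte and its granulosa cells, was at 12.2, 133 and 134 FPKM, with a log2 ratio of 3.35 at either dose, although its 2 rows gave 2.80, 126 and 124 FPKM and 9.36, 7.34 and 9.15 FPKM. Both exposed libraries were also higher for Igf2bp1 (0.44, 65.9 and 25.9 FPKM), the receptor Ephb4 (0.83, 49.0 and 30.5 FPKM), the ADP-ribosyltransferase Parp14 (4.47, 119 and 93.8 FPKM), Sulf2 (1.12, 24.0 and 69.1 FPKM), Gbas (5.91, 75.5 and 98.4 FPKM) and the glycogen phosphorylase Pygl (0.83, 23.2 and 17.7 FPKM). Oser1, a gene that responds to oxidative stress, was at 550.2, 48.9 and 53.4 FPKM, Tuba1c at 48.8, 4.83 and 1.00 FPKM, Smim20 at 41.6, 3.11 and 4.10 FPKM, Rab9 at 18.2, 1.56 and 1.55 FPKM and Rpp25l at 71.5, 10.4 and 4.42 FPKM. Rn18s-rs5, related to ribosomal RNA, was at 21.6, 2.04 and 1.21 FPKM. Within Rc3h1 the difference lay in 1 row (0.24, 66.3 and 67.1 FPKM) and not in the other (1.18, 1.65 and 1.19 FPKM), and within Tead1 in a row at 41.8, 0.17 and 0 FPKM. The largest row of Pygl was listed at 0 in control.

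In total 678 genes were at least 2-fold higher and 236 at least 2-fold lower in both exposed libraries. Both comparisons shared the single control library, which gives overlap with no effect. Across 100 simulations of exchangeable libraries, 838 genes on average (range 782 to 899) passed the rule in the same direction at both doses, against 914 observed. By direction, 678 higher genes stood against 425 simulated (386 to 463) and 236 lower genes against 413 simulated (373 to 450), so the higher genes exceeded the simulation and the lower genes fell short of it. After trimmed mean scaling 853 genes passed against 783 simulated on scaled values (729 to 843), with 566 higher and 287 lower. With ratios adjusted for length 779 genes passed, a case that was not simulated. The simulation holds no shift between libraries and treats genes as independent. Its range thus leaves out differences that run through a whole library and genes that vary together. That range is too narrow to decide whether the observed overlap exceeds that of exchangeable libraries, so no excess is concluded from it. Independent lists, which ignore the shared control, would share 168 higher and 36.8 lower genes. The log2 ratios of the 2 doses correlated across genes at Pearson r = 0.52 (0.50 simulated) and Spearman rho = 0.55 (0.46 simulated), with a covariance of 0.45 against 0.44 simulated, and genes are not independent replicates. Because the control could not be divided, part of any excess may come from the shared control.

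The high dose library was compared with the low dose library for the difference between the doses. Cholesterol and steroid synthesis genes were lower as a group at the high dose, and ubiquitin-proteasome genes higher. Both calls ended under several of the alternatives given below. Mos was at 8.57 FPKM at the high dose against 178 FPKM at the low dose (log2 ratio -4.22), and Gdf9 at 193 against 38.5 FPKM (2.29). Of the expressed genes, 741 were at least 2-fold higher and 1182 at least 2-fold lower at the high dose, and the median of all genes was -0.07. Trimmed mean scaling gave 792 higher and 997 lower, with a median of 0.01.

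Single genes with the largest positive ratios were Tmem261 (98.6 against 0.35 FPKM, 6.21), Usp50 (68.9 against 0.16, 5.91), Uevld (125 against 1.24, 5.82), the phosphatase Dupd1 (37.7 against 0.090, 5.15), Rpp38 (108 against 2.13, 5.12) and Hist1h2bc (62.2 against 0.96, 5.01). Gart, an enzyme of purine synthesis (53.8 against 0.91, 4.85), Hgsnat (4.79) and Heg1 (25.2 against 0.025, 4.68) followed, with Muc13 listed at 0 in the low dose library. The largest negative ratios were those of Ccnk (2.31 against 265 FPKM, -6.33), Dytn (-5.50), Ccdc6 (-5.42), Sall4 (0.43 against 54.6, -5.28), the ADP-ribosyltransferase Parp12 (0.68 against 63.7, -5.27), Fam76a (-5.08) and Dpm3, a subunit of dolichol-phosphate mannose synthase (0.40 against 33.8, -4.63). Sf3b5, a splicing factor subunit, was listed at 0, 24.1 and 0 FPKM. Pcbp1 and mt-Tf, also listed at 0 at the high dose, completed the 10 on the lower side. The largest row was listed at 0 at the low dose for Uevld, Dupd1, Gart and Heg1 and at the high dose for Ccnk, Fam76a and Cyp11a1. Several rows or a single exon were found for 6 of the 10 genes on either side.

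Cholesterol and steroid synthesis genes (16 expressed, 0 higher and 3 lower) had a median of -0.39 at percentile 1.69. Hmgcs1, an early enzyme of the mevalonate pathway, was at 77.2, 123 and 23.5 FPKM, Pmvk at 3.39, 1.52 and 0.49 FPKM and Cyp11a1 at 3.55, 7.51 and 0.44 FPKM. Against control the medians of this list were 0.46 and 0.14, at percentiles 92.1 and 62.9. Its low dose percentile passed the upper limit with rows kept separate (99.24), the largest row per gene (99.29) and rows in all 3 tables only (98.75). Proteasome genes had a median of 0.14 at percentile 98.4, with 0 of 32 past the rule. Between the doses the cholesterol list no longer stood apart with the largest row per gene (percentile 6.28), without a filter on low values (17.2) or with a mean of at least 5 FPKM (13.6). The same held with rows kept separate (7.96), with rows in all 3 tables only (5.59) and with ratios adjusted for length (2.95). The proteasome list no longer did when length was matched (97.1), with ratios adjusted for length (95.2) or with genes held by 1 list only (97.49).

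The order of the doses was described by the library that lay between the others. The low dose library was the middle one for 28.0% of expressed genes (95% exact binomial interval 27.2 to 28.8), the control for 26.9% and the high dose library for 45.1%, where exchangeable libraries give 33.3%. Of the 3660 genes with at least 2-fold between the highest and the lowest library, the high dose library lay in the middle for 45.8% and the low dose library for 24.9%. For Gdf9 (661, 38.5 and 193 FPKM) the high dose library lay in the middle, and for Ahr (2.21, 3.86 and 5.85 FPKM) the low dose library. Intervals treat genes as independent, which they are not.

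Markers of other ovarian cells were at 23.9 FPKM or below in all 3 libraries. Of the cumulus and granulosa list 5 genes were expressed, none above 17.0 FPKM. Nr5a2 was at 17.0, 13.2 and 10.6 FPKM, Fshr, the receptor of follicle-stimulating hormone, at 5.61, 9.95 and 9.05 FPKM, Inha at 0.38, 2.55 and 1.03 FPKM and Cyp19a1, aromatase, at 1.42, 1.32 and 2.22 FPKM. The median log2 ratios of this list were -0.03 and 0.41, at percentiles 27.6 and 87.3. Theca, stroma and fibroblast markers reached at most 0.17 FPKM, with Dcn at 0.16, 0.011 and 0.045 FPKM. Of expanded cumulus markers 2 genes were expressed, Cyp11a1 at 3.55, 7.51 and 0.44 FPKM and Lhcgr, the receptor of luteinising hormone, at 0.085, 3.86 and 1.61 FPKM. C1qb, a complement gene of macrophages, was at 23.9, 8.79 and 10.8 FPKM and Itgam at 0.72, 3.14 and 0.71 FPKM. Endothelial markers with a mean of at least 1 FPKM were Pecam1 (2.66, 3.96 and 3.30 FPKM), Vwf (2.36, 4.92 and 2.40 FPKM) and Tek (1.07, 2.11 and 1.28 FPKM). Among epithelial markers Cdh1, E-cadherin, which oocytes also express, was at 12.5, 20.4 and 20.7 FPKM, Krt8 at 1.75, 1.75 and 1.44 FPKM and Upk3b at 1.73, 0.38 and 1.64 FPKM.

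Of 15 expressed housekeeping reference genes, 3 were higher than control at the low dose and 2 at the high dose, and the list did not stand apart in the main setting. Actb, cytoplasmic actin, was at 48.3, 128 and 106 FPKM, with log2 ratios to control of 1.39 and 1.12, Ppia, cyclophilin A, at 40.8, 109 and 104 FPKM, with 1.39 and 1.33, and Tfrc, the transferrin receptor, at 1.73, 6.91 and 2.95 FPKM. The medians of the list were 0.31 and 0.20, at percentiles 83.6 and 84.7. With genes held by 1 list only, the list stood apart at the high dose (percentile 97.75).

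Differences from control also moved with transcript length. Among 11717 genes with an annotated length, the median log2 ratio at the low dose was -0.02 in the fifth of genes with the shortest transcripts and 0.38 in the fifth with the longest. At the high dose these values were -0.03 and 0.22. Across genes, transcript length correlated with the log2 ratio at Spearman rho = 0.22 for the low dose, 0.17 for the high dose and -0.10 between the doses.

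**Figure D4:**
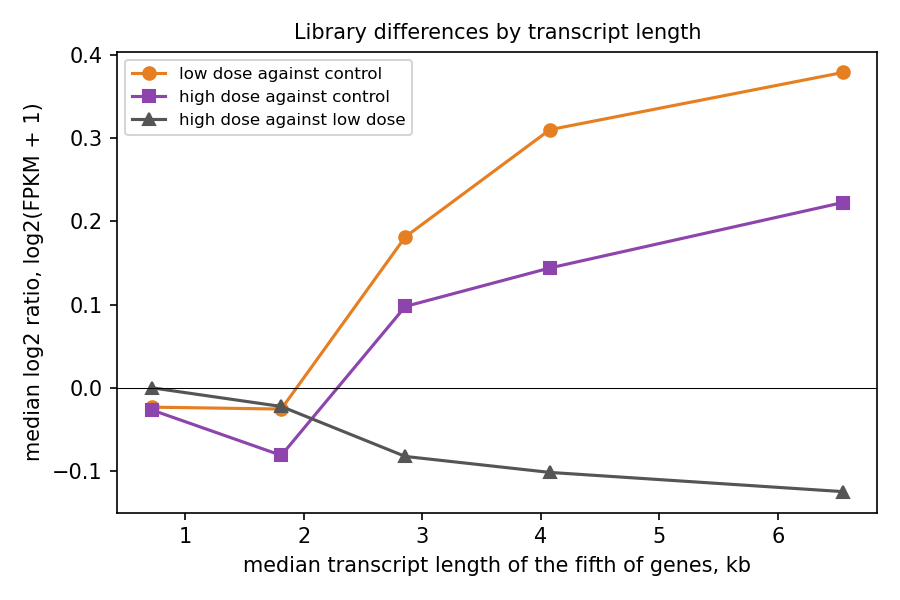
Median log2 ratio, on the log2(FPKM + 1) scale, of genes in 5 groups of transcript length (horizontal axis, median length of each group in kb) for the low dose against control, the high dose against control and the high dose against the low dose; each point is 1 group of 2343 or 2344 genes, with no error bar. The low dose line goes from -0.02 to 0.38 and the high dose line from -0.03 to 0.22.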

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

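The tests of a few abundant rows, of sequencing depth and of unspliced or genomic sequence at the high dose were chosen only after the result was seen.

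Rows without a gene name, which the comparisons of the report do not use, held 21.9% of the FPKM in the low dose library and 19.3% in the high dose library, above the 15.4% of the control library, and had median log2 ratios to control of 0.26 and 0.18. The 20 unnamed rows with the largest gains held 22.2% of the net gain at the low dose and 21.3% at the high dose. This argues against a few abundant rows as the main source of the gain. Without these rows the median of unnamed rows exceeded that of named genes by 0.097 (95% bootstrap interval 0.063 to 0.126) at the low dose. At the high dose the excess was 0.105 (0.079 to 0.134). Leaving out 20 of 7242 rows can hardly move a median (0.26 with and without them at the low dose), so these excesses do not test that explanation. Reads from unspliced or genomic sequence could raise such rows, but the smaller rows of named genes exceeded the largest rows by 0.016 at the low dose, with an interval of -0.032 to 0.061 that spans the bound of 0.05 set beforehand, so this stays open at the low dose. At the high dose the smaller rows differed from the largest rows by -0.0322 (interval -0.061 to 0.009), with no excess past that bound. Smaller and largest rows alike lay above the median of named genes there (0.14 and 0.17 against 0.08). A comparison of 2 raised groups cannot decide the question, so unspliced or genomic sequence stays open at the high dose too. Depth cannot be told apart from the group, because the low dose library had 0.803 of the control's estimated depth and the share ran against depth in all 3 libraries. The exposure itself stays open as an untested explanation, and the shares did not follow the order of the doses.

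At least 2-fold higher at 1 dose and at least 2-fold lower at the other were 59 genes, in opposite directions against the shared control, where simulated exchangeable libraries gave 66.0 on average (range 56 to 83); with 1 library per group this difference was not tested. Parp12 (10.4, 63.7 and 0.68 FPKM), Uhrf1 (54.6, 126 and 5.72 FPKM), Ccnk (75.6, 265 and 2.31 FPKM), Tcl1 (202, 95.3 and 609 FPKM) and Dupd1 (4.54, 0.090 and 37.7 FPKM) were among them.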

How the results depend on the processing

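The alternatives with the largest row per gene, rows in all 3 tables only, unnamed rows added, ratios adjusted for length and lists matched on length were chosen only after the result was seen. The counts depend on the size rule, the pseudocount and the filter, which set how many genes can pass, and the cause of other shifts was not tested. In the order low dose, high dose, high against low dose and same direction at both doses, 4816, 3842, 3628 and 2177 genes passed a 1.5-fold rule and 649, 494, 592 and 202 a 4-fold rule. A pseudocount of 5 gave 1057, 773, 822 and 379 genes, a mean of at least 5 FPKM 1341, 990, 951 and 554, and unnamed rows added 4767, 3538, 3801 and 1824. A pseudocount of 0.1 gave 2732 genes at the high dose and 1475 in the same direction. The low dose library was the middle one for 29.7% of genes under median-of-ratios scaling, 29.7% under trimmed mean scaling, 29.7% under scaling without the most abundant genes and 29.3% with ratios adjusted for length.

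Ratios adjusted for length gave 2, 1 and 1 lists standing apart in the 3 comparisons, and matching on length left 2 at the high dose and 1 between the doses. Between the doses 1 list stood apart without a filter on low values, 1 with genes held by 1 list only, 1 with the largest row per gene and 1 with rows in all 3 tables. Over all alternatives the percentile of a list stayed on its side of the limits in 962 cases, left the outer range in 23 and entered it in 14. Most of the 962 cases were lists without a call, since 4, 4 and 2 lists stood apart in the 3 comparisons of the main setting. Scaling a whole library hardly moves a list among random lists, and each of the 3 scalings left all 72 percentiles on their side. The total is thus no measure of how stable the calls were. The correlation of the doses moved by under 0.1 in every alternative run on it. With the largest row per gene Kif4 turned to log2 ratios of 0.36 at the low dose and 0.12 at the high dose, and Tet1 to -1.28 at the high dose and -0.38 between the doses, because other rows of these genes hold the rest of their values. Under the same alternative 13 ratios no longer passed the 2-fold rule. Against control these were Ahr (0.83), Bmp15 (0.71) and Lhcgr (0.85) at the high dose and Tet2 (0.52), Ncor1 (0.38), Itgam (0.36), Vdac1 (-0.17) and Hspb1 (-0.73) at the low dose. Antioxidant genes at the low dose (percentile 3.92) and histone-modifying enzymes at the high dose (97.4) also came inside. No table in a second unit or of counts was analysed here, so that alternative was not run. No paired analysis was possible because each group had 1 library. Depth of 27900000 to 34700000 reads limits counting error alone, and the missing replicates limit every comparison.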

Other observations

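The tests of rows assembled within or beside a gene, of read numbers and of neighbouring genes, and both corrections for transcript length, were chosen only after the result was seen.

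The apoptosis, DNA repair, unfolded protein response and autophagy lists did not stand apart in either exposed library. Apoptosis genes (12 expressed) had 0 higher and 0 lower at the low dose and 1 higher at the high dose, Bcl2l1, an inhibitor of apoptosis, at 1.38, 0.96 and 7.19 FPKM. Bad was at 2.49, 1.11 and 1.87 FPKM, Birc5, survivin, at 173, 105 and 128 FPKM and Cflar at 0.71, 2.01 and 1.42 FPKM, and the list medians were 0.28 and -0.02 at percentiles 70 and 29.5. DNA repair genes (29 expressed) had medians of 0.30 and 0.21 at percentiles 78.9 and 84.8, with Apex1, an endonuclease of base excision repair, at 26.3, 5.78 and 12.9 FPKM, the uracil glycosylase Ung at 0.32, 2.39 and 5.56 FPKM and Rad51c at 30.5, 18.2 and 53.7 FPKM. H2afx was at 14.9 FPKM at the high dose, listed at 0 at the low dose and taken as 0 in control. Genes of the unfolded protein response (24 expressed) had medians of 0.02, or -0.15 under trimmed mean scaling, and -0.07, at percentiles 34.8 and 20.7. Its transcription factors moved at different doses, Ddit3 being at 57.8, 10.6 and 39.3 FPKM and Atf4 at 21.0, 31.5 and 5.64 FPKM. Eif2a was at 3.83, 19.6 and 5.38 FPKM and Hspb1 at 4.88, 1.28 and 8.63 FPKM. Autophagy genes (19 expressed) had medians of -0.10 and -0.06 at percentiles 7.48 and 17.3. Map1lc3a, an LC3 protein of autophagosomes, was lower at both doses at 24.3, 2.74 and 3.77 FPKM, Atg14 was higher at 15.1, 44.6 and 39.2 FPKM, Lamp1 was at 31.5, 34.2 and 4.77 FPKM and Ambra1 at 23.8, 19.7 and 9.55 FPKM. The largest Ambra1 row was at 17.7, 8.94 and 0.41 FPKM. Its other rows were at 2.40, 10.2 and 4.81 FPKM and at 3.75, 0.53 and 4.33 FPKM.

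The glycolysis, mitochondrial dynamics, imprinted and 2-cell lists lay within the range of random lists against control in the main setting. Glycolysis and tricarboxylic acid genes (25 expressed) had medians of 0.08, or -0.07 under trimmed mean scaling, and -0.04, at percentiles 30.7 and 19.9. Mdh2, mitochondrial malate dehydrogenase, was at 36.8, 12.5 and 13.6 FPKM, Gpi1 at 2.39, 0.62 and 3.89 FPKM, Idh3g at 13.5, 6.84 and 6.72 FPKM and Ldha at 2.93, 6.01 and 3.48 FPKM. Mitochondrial dynamics genes (19 expressed) had medians of 0.11, or -0.05 under trimmed mean scaling, and 0.10, at percentiles 38 and 57. With a mean of at least 5 FPKM this list stood apart at the low dose (percentile 0.825). Fis1, which acts in mitochondrial fission, was at 46.2, 16.9 and 33.0 FPKM, Opa1, which acts in fusion, at 6.27, 6.82 and 18.96 FPKM, Tfb2m at 0.33, 3.63 and 0.55 FPKM and Vdac1 at 10.1, 4.50 and 6.26 FPKM. Imprinted genes (18 expressed, 3 higher and 1 lower at the low dose, 2 and 0 at the high dose) had medians of 0.25 and 0.14 at percentiles 67.1 and 67.3. Usp29 was at 13.8, 66.3 and 26.7 FPKM, Inpp5f at 7.58, 41.3 and 27.8 FPKM, Igf2r at 1.75, 4.77 and 7.77 FPKM and Plagl1 at 12.3, 3.24 and 16.2 FPKM. Genes of the 2-cell stage (6 expressed) had medians of -0.37 and -0.18 at percentiles 5.43 and 14.5, with Klf17 at 8.34, 1.37 and 1.15 FPKM, Tcstv1 at 120.3, 61.6 and 74.7 FPKM, Eif1a at 2.02, 1.22 and 2.75 FPKM and Eif1ad at 4.53, 6.30 and 5.11 FPKM.

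The lists that stood apart against control may owe part of their shift to the length trend between libraries, because the median transcript lengths are 1831 bases for oocyte-specific factors, 1705 for the proteasome and 4663 for histone-modifying enzymes. With random lists matched on length too, the percentiles at the low dose were 0.22 for the proteasome, 1.74 for oocyte-specific factors, 2.22 for antioxidant genes and 94.7 for histone-modifying enzymes, and at the high dose 4.79, 4.87, 2.21 and 97.7. Ratios adjusted for length gave 1.36, 7.07, 6.69 and 94.2 at the low dose and 2.27, 2.98, 6.0 and 94.1 at the high dose. Length alone is argued against for the proteasome at the low dose, which stayed outside under both corrections, while histone-modifying enzymes at the low dose and oocyte-specific factors at the high dose came inside under both. For the other 5 cases the corrections differed or lay near the limit, so length and the exposure stay open.

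Differences of 8-fold or more between libraries occurred at 208 of 5304 protein-coding genes with a mean of at least 5 FPKM. Rows assembled within or beside a gene are a candidate explanation, since 70.2% of the 208 were single-exon or had several rows, against 38.1% of the other genes and an upper limit of 46.6% in the central 95% of matched random sets. The number of reads was not decided, since the filter on the mean fixes the outcome of that test. Reads were not counted but worked out from the summed FPKM, the longest transcript and the estimated depth. So derived, the highest library's value stood for a median of 3689 and a 5th percentile of 641 reads. Lengths of the assembled rows were not known, and a row shorter than that transcript would hold fewer reads. Reads were also not told apart from copies of few molecules. Exchange of reads with named, expressed neighbours was not decided. Of 88 such neighbours within 3 kb, 43.2% moved in the opposite direction by any amount (95% exact interval 32.7 to 54.2). Opposite movement thus did not prevail among these neighbours. The share among neighbours of other genes was not worked out, and genes without such a neighbour were not covered. Rows without a gene name were not among these neighbours, so exchange with them stays open too. The exposure stays open as an untested explanation, and replicate libraries or read-level coverage were not analysed here.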
